A study of Homo sapiens with 8 samples.

How the data were processed

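RNA-seq libraries of HCT116 cells were compared, 4 untreated and 4 treated with CB-5083. Groups and replicate numbers were taken from the sample titles and the treatment tags; 0 columns were left without a sample. The deposited files hold 1 estimated count (read count) per gene and library with no normalization, per the file headers; 11.9% of values in the untreated and 11.0% in the CB-5083 libraries were not whole, as can arise when reads are shared out between genes. Alignment with HISAT2 is named in the submitters' processing notes, as is the genome build mm10. That build is a mouse build, whereas the files carry human Entrez gene identifiers and symbols, so the build behind the counts is uncertain and no genomic coordinates are printed. The counting tool, its version, the gene annotation and whether strand was used are not given in the sources used here, so reads of overlapping and antisense genes cannot be told apart. All 16488 gene entries in the files are of type mRNA, 569 of them with no read in any library. Totals per library ranged from 13109118 to 16863894 counts.

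The expected counts were rounded to whole numbers. Genes were kept by edgeR's filterByExpr by group (min.count 10, min.total.count 15), which left 12760. Counts were scaled by TMM and tested with edgeR's quasi-likelihood F test (glmQLFit with robust = TRUE, glmQLFTest, two-sided) on group alone, with Benjamini-Hochberg adjustment over all tested genes and a threshold of 0.05. The standard error (SE) of a log2 change was the absolute change divided by the square root of the F statistic. Counts-per-million (CPM) values are TMM-scaled means ± SD over 4 libraries. The biological coefficient of variation was 4.56%, so changes well below 2-fold could pass. The median log2 change of all tested genes was -0.00325 with TMM and -0.0133 with library totals alone. Versions were R 4.3.3, edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0.

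A total of 30 pathway lists and 6 lists of markers of other cell types were written before the data were examined. Lists with at least 5 tested members were tested with limma's camera on log2 CPM (prior count 2) with a preset correlation of 0.01, again with an estimated correlation, and with fry, which asks whether the genes of a list move on balance one way without comparing them with other genes. Adjustment was over the 29 lists that could be tested. Genes were also counted as risen or fallen over all tested genes and after adjustment over the list alone. The list of the mitochondrially encoded genes had no tested member. Genes were named by a rule fixed at the same time: VCP; the 10 largest increases and the 10 largest decreases among genes that passed, had a mean of at least 10 CPM and had all CB-5083 libraries on one side of all untreated ones; and from each list the 2 largest passing changes in its more frequent direction and the 1 largest in the other. This gave 96 genes, a few of which are not reported here. A few further genes are marked as chosen after their values were seen. Genes with non-whole counts in any library, 18.3% of those tested and 13 of the 96 named genes, may share reads with a copy or an overlapping gene and are uncertain; the text gives the number of libraries beside each one it names.

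Replicates were compared by a chi-square test of their counts over genes. The statistic per degree of freedom was 2.89 to 5.10 between untreated and 1.75 to 2.79 between CB-5083 libraries, so no pair was treated as one library. Single values were compared with two-sided exact permutation tests. The pipeline was tested on simulated counts for the 12760 genes, with 50 changed genes at each fold. It called 70% of genes changed 1.25-fold, 85.7% of those changed 1.5-fold, 94% at 2-fold and 100% at 3-fold, and 13 of 12530 unchanged genes, counting those that passed the filter. In the simulation 200 genes were changed and 30 more shifted as a list, whereas 54.9% of tested genes passed in the data. With so few changed genes the adjusted threshold is stricter, so these shares do not give the sensitivity in the data.

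Alternatives fixed before the data were examined were DESeq2's size factors, library totals alone, the DESeq2 Wald test, limma-voom, no low-count filter, a filter of at least 1 CPM in 4 libraries, the replicate number as a block, each library left out in turn, estimated correlations and fry. Correction for GC content and transcript length (a loess trend per library, with GENCODE 29 transcripts; 99.4% of tested genes had values), counts thinned to the smallest total, unrounded counts, and the removal of genes with non-whole counts were added after the data were seen. MTRNR2L transcripts were aligned to the mitochondrial 16S rRNA with BLAST+ 2.17.0.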

Results

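Gene expression was measured by RNA-seq in HCT116 cells, an established human colorectal cancer cell line, either left untreated (4 libraries) or exposed to CB-5083 (4 libraries). CB-5083 is an inhibitor of VCP (also called p97), an ATPase that extracts ubiquitinated proteins from membranes and complexes so that the proteasome can degrade them. The single comparison in the design asks which genes differ in expression between treated and untreated cells. Dose and exposure time are not given in the sources used here. The sample titles and treatment tags name the 2 groups, whereas another label calls all 8 samples control; the titles and treatment tags were used. Library totals ranged from 13109118 to 16863894 counts over 16488 genes listed as mRNA. Totals were higher in the untreated libraries (mean 15887733 ± 930653, SD, n = 4) than in the CB-5083 libraries (13377723 ± 275619, SD, n = 4; two-sided exact permutation p = 0.0286, the smallest that 4 against 4 can give). Counts assigned to the MTRNR2L genes, nuclear copies of the mitochondrial 16S rRNA gene, made up 1.29 ± 0.0576% of the untreated and 1.11 ± 0.0351% of the CB-5083 totals (SD, n = 4 each; exact permutation p = 0.0286). No replicate pair agreed within sampling noise. Nothing in the labels says that the replicates came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

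VCP itself (Gene ID 7415), the target of the compound, rose from 326 ± 13.6 to 461 ± 8.14 counts-per-million (CPM; SD, n = 4 each), a 1.41-fold increase (log2 change 0.50 ± 0.0358 SE, adjusted p = 2.07e-15 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). The largest increase among genes with a mean of at least 10 CPM was that of ATF3 (Gene ID 467), a stress-induced transcription factor, from 8.35 ± 0.376 to 69.7 ± 3.76 CPM (log2 change 3.06 ± 0.0724 SE). GDF15 (Gene ID 9518), a secreted stress cytokine, rose from 35.2 ± 2.20 to 261 ± 4.22 CPM, 7.41-fold. CDKN1A (Gene ID 1026), which encodes the cyclin-dependent kinase inhibitor p21, rose from 73.2 ± 5.49 to 484 ± 8.99 CPM, 6.62-fold. KRT7, an epithelial keratin, rose 5.98-fold to 85.4 ± 7.77 CPM, and JUN, a subunit of the AP-1 transcription factor, rose 5.73-fold to 36.8 ± 0.934 CPM. CPA4, HSPB8, DDIT3 and KRT80 were also among the 10 largest increases, with log2 changes of 2.08, 2.03, 2.00 and 1.84. KRT7, CPA4 and KRT80 were in none of the gene lists fixed before the data were examined.

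ADAM19, a membrane metalloprotease, fell the most among genes with a mean of at least 10 CPM over all 8 libraries. It went from 101 ± 6.62 to 38.1 ± 2.51 CPM (log2 change -1.41 ± 0.0559 SE, edgeR adjusted p = 1.46e-23). CENPW, a centromere protein, fell from 16.4 ± 0.595 to 6.58 ± 0.732 CPM, and SPC25, a component of the kinetochore NDC80 complex, from 43.3 ± 1.28 to 18.3 ± 1.75 CPM. PCLAF, a PCNA-binding factor, fell from 73.6 ± 1.70 to 30.7 ± 2.47 CPM, and CHTF18, a subunit of an alternative clamp loader, from 43.6 ± 5.88 to 19.0 ± 1.88 CPM. ARHGEF39, SESTD1, TNS2 and KLF7 were also among the 10 largest decreases, with log2 changes of -1.30, -1.20, -1.18 and -1.17. None of these genes was in a fixed list. Non-whole counts, which may mark reads shared with another gene, occurred in all 8 libraries for ARHGEF39 and SPC25 and in 1 library for PCLAF, so these values are uncertain.

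**Figure D1:**
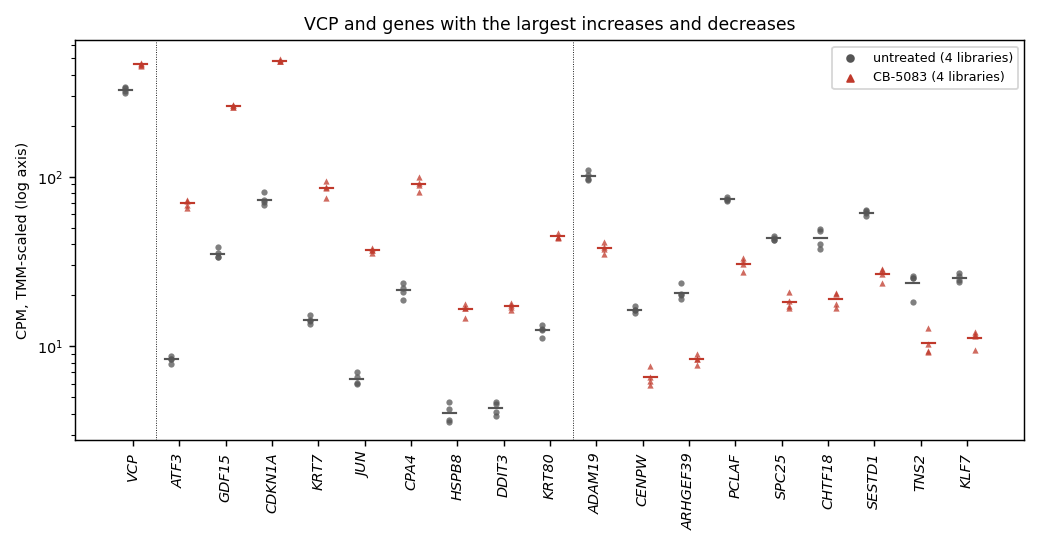
Expression of VCP and of genes among the 10 largest increases (left) and the 10 largest decreases (right). The y axis gives TMM-scaled CPM on a log scale; each circle (untreated) or triangle (CB-5083) is 1 library, and the horizontal bar is the mean of the 4 libraries. All 4 CB-5083 libraries lay on one side of all 4 untreated libraries for each gene. For all genes but VCP this was a condition of their choice. ATF3, for example, went from a mean of 8.35 to 69.7 CPM.

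Across the 12760 genes tested, 3504 were higher and 3498 lower with CB-5083 at an adjusted p under 0.05 by edgeR's quasi-likelihood test. Most changes were small. The median absolute log2 change of the called genes was 0.335, and 2442 of them changed by less than 1.2-fold. An increase of 2-fold or more was found for 210 genes and a decrease of that size for 165. With no low-count filter these numbers were 294 and 267. In 47.3% of the tested genes all CB-5083 libraries lay on one side of all untreated libraries, against 2.86% by chance. The first principal component, which carried 61.9% of the variance, separated the groups.

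Targets of the integrated stress response, the ATF4 branch of the response to endoplasmic reticulum (ER) and amino acid stress, rose almost throughout. Of 31 tested members 30 rose and none fell (31 rose adjusted over the list alone), with a median log2 change of 0.75. Besides ATF3 and GDF15, DDIT3, which encodes the pro-apoptotic factor CHOP, rose from 4.32 ± 0.396 to 17.3 ± 0.743 CPM (SD, n = 4). SHMT2, a mitochondrial enzyme of serine and glycine metabolism, was the member that did not pass over all genes, with a log2 change of 0.08 ± 0.0391 SE and an edgeR adjusted p of 0.0693. The list was called by camera, a test of a list against all other genes (adjusted p = 1.64e-17, and adjusted p = 0.015 with an estimated correlation). The aminoacyl-tRNA synthetases, which load amino acids onto tRNAs, had 14 of 20 tested members up and 2 down (14 and 2 adjusted over the list alone). AARS1 rose from 218 ± 2.42 to 376 ± 6.91 CPM and SARS1 from 133 ± 4.74 to 215 ± 4.74 CPM, while FARSB fell by 0.21 on the log2 scale. That list passed camera with the preset correlation (adjusted p = 0.000277) but not otherwise (adjusted p = 0.074 with an estimated correlation).

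Most ER chaperone and folding genes driven by ATF6 and IRE1-XBP1 rose. In that list 23 of 32 tested members rose and 3 fell (23 and 3 adjusted over the list alone), and the median log2 change was 0.23. HERPUD1, a scaffold of ER-associated degradation, rose from 38.7 ± 2.15 to 70.1 ± 2.42 CPM (SD, n = 4), and EDEM2, a mannosidase acting on misfolded glycoproteins, from 14.2 ± 0.545 to 23.0 ± 1.69 CPM, with non-whole counts in 2 libraries. HSPA5, the ER chaperone BiP, chosen after its values were seen, rose from 1002 ± 48.4 to 1528 ± 32.0 CPM (log2 change 0.61). SDF2L1, an ER chaperone cofactor, fell by 0.26 on the log2 scale (edgeR adjusted p = 0.0275). Its log2 change was -0.17 without CB-5083 replicate 2. The SDF2L1 call was lost without untreated replicate 1 (edgeR adjusted p = 0.0523), untreated replicate 2 (0.105), CB-5083 replicate 1 (0.0552), CB-5083 replicate 2 (0.175) or CB-5083 replicate 3 (0.0563), and after correction for GC content and length (0.0686). The camera call of the list (adjusted p = 5.27e-05) was lost with the correlation estimated (adjusted p = 0.074 with an estimated correlation).

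Among components of ER-associated degradation, 10 of 25 tested genes rose and 3 fell (10 and 3 adjusted over the list alone). SYVN1, the ubiquitin ligase HRD1, rose from 29.9 ± 3.30 to 41.4 ± 2.23 CPM and FBXO2, a subunit of a ligase that recognises glycoproteins, from 80.3 ± 8.28 to 104 ± 8.28 CPM (SD, n = 4). TMUB1 fell from 26.4 ± 2.29 to 17.2 ± 0.479 CPM. Camera called the list with the preset correlation (adjusted p = 0.0174; adjusted p = 0.074 with an estimated correlation). VCP and its cofactors had 17 of 31 tested members up and 5 down (18 and 6 adjusted over the list alone), with a median log2 change of 0.14. ZFAND2A, a stress-inducible partner of the proteasome, rose from 9.02 ± 0.76 to 13.95 ± 2.02 CPM, with a non-whole count in 1 library. NPLOC4 and NSFL1C, which encode the VCP adaptors NPL4 and p47 and were chosen after their values were seen, each rose by a log2 change of 0.43. SVIP, a small inhibitor of ER-associated degradation, fell from 24.5 ± 1.97 to 18.0 ± 0.594 CPM. The camera call of this list (adjusted p = 0.0284) was also lost (adjusted p = 0.12 with an estimated correlation).

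Proteasome subunits and assembly factors rose slightly: 24 of 40 tested members rose and 4 fell (25 and 4 adjusted over the list alone), with a median log2 change of 0.13. PSMC4, an ATPase of the regulatory particle, rose from 90.3 ± 6.21 to 132 ± 7.41 CPM (SD, n = 4). PSMG1, an assembly chaperone, fell by 0.41 on the log2 scale. Camera called this list (adjusted p = 0.000522, and adjusted p = 0.024 with an estimated correlation). Genes of the heat shock response did not move one way. HSPB8, a small heat shock protein, rose 4.09-fold to 16.5 ± 1.27 CPM and DNAJB4 rose 1.75-fold to 51.1 ± 3.25 CPM, whereas HSPE1, the mitochondrial chaperonin cofactor, fell from 239 ± 24.6 to 126 ± 10.2 CPM, with non-whole counts in all 8 libraries. Of 25 tested heat shock genes 10 rose and 8 fell (10 and 8 adjusted over the list alone; camera adjusted p = 0.848). HSPA1B, an inducible HSP70 gene chosen after its values were seen, was at 233 ± 11.8 and 239 ± 11.9 CPM (edgeR adjusted p = 0.469). It had non-whole counts in 7 libraries.

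Autophagy genes rose, with 23 of 31 tested members up and 1 down (23 and 1 adjusted over the list alone) and a median log2 change of 0.38. SQSTM1, which encodes the autophagy receptor p62, rose from 303 ± 18.3 to 778 ± 30.5 CPM, although it had non-whole counts in all 8 libraries. GABARAPL1, an ATG8 family member of the autophagosome membrane, rose from 30.2 ± 0.659 to 74.1 ± 1.02 CPM, and ATG3, which conjugates ATG8 proteins to lipid, fell by 0.21 on the log2 scale. Camera gave an adjusted p of 1.46e-07 (adjusted p = 0.024 with an estimated correlation). Lysosomal genes went both ways: 15 of 36 tested rose and 11 fell (15 and 11 adjusted over the list alone; camera adjusted p = 0.311). PSAP, the precursor of the saposins, rose from 446 ± 15.4 to 899 ± 29.2 CPM (SD, n = 4). GPNMB, at 1.35 ± 0.351 and 2.15 ± 0.719 CPM, rose by a log2 change of 0.66 (edgeR adjusted p = 0.0342). This call was lost without untreated replicate 2 (0.109), untreated replicate 4 (0.0808), CB-5083 replicate 2 (0.0547) or CB-5083 replicate 4 (0.233), and with DESeq2 (0.0659), all adjusted p. Without CB-5083 replicate 4 the log2 change of GPNMB was 0.42.

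NRF2 targets, genes of antioxidant defence and iron storage, had 23 of 28 tested members up and 2 down (23 and 2 adjusted over the list alone), with a median log2 change of 0.29. FTL, the ferritin light chain, rose from 641 ± 50.5 to 1429 ± 31.6 CPM (SD, n = 4). AKR1B10, an aldo-keto reductase, rose from 0.307 ± 0.194 to 2.09 ± 0.416 CPM, on 20 and 111 counts summed over 4 libraries each. ABCC2, a drug efflux transporter, fell by 0.39 on the log2 scale. The list was called by camera (adjusted p = 4.85e-07, and adjusted p = 0.024 with an estimated correlation). Metallothioneins bind zinc and copper, and their list also holds the transporter genes SLC30A1 and SLC30A10 and the transcription factor gene MTF1. Of 6 tested members of this list 3 fell and none rose (0 and 3 adjusted over the list alone, camera adjusted p = 0.236). MT1X fell from 11.1 ± 1.66 to 5.51 ± 0.477 CPM, and MT1F fell from 1.12 ± 0.235 to 0.448 ± 0.255 CPM on 71 and 24 summed counts.

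Targets of the tumour suppressor p53 rose together. Of 32 tested members 31 rose and none fell (31 rose and 1 fell adjusted over the list alone), and the median log2 change was 0.98. CDKN1A rose 6.62-fold, and SPATA18, an inducer of mitochondrial quality control, rose from 0.174 ± 0.0383 to 1.29 ± 0.499 CPM on 11 and 69 summed counts. MDM2, the ubiquitin ligase of p53, chosen after its values were seen, rose from 216 ± 9.04 to 561 ± 38.2 CPM, with non-whole counts in 6 libraries. PERP, a p53 target of cell adhesion, was the member that did not pass over all genes (log2 change -0.09 ± 0.0438 SE, edgeR adjusted p = 0.0847). Camera called the list (adjusted p = 4.64e-18, and adjusted p = 0.0015 with an estimated correlation). Apoptosis regulators had 11 of 30 tested members up and 4 down (11 and 4 adjusted over the list alone; camera adjusted p = 0.126). CASP10, an initiator caspase, rose from 3.12 ± 0.558 to 6.53 ± 0.585 CPM and PMAIP1, the BH3-only protein NOXA, from 54.7 ± 2.46 to 96.2 ± 3.83 CPM (SD, n = 4). BCL2, an anti-apoptotic gene, fell from 4.73 ± 0.265 to 2.65 ± 0.466 CPM.

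Genes of the G1/S and G2/M lists fell almost without exception. All 40 tested genes of G2/M and mitosis fell (40 adjusted over the list alone), with a median log2 change of -0.82, and 41 of 42 tested genes of G1/S and DNA replication fell and none rose (41 adjusted over the list alone), with a median of -0.68. CENPA, the centromeric histone H3 variant, fell from 17.9 ± 0.714 to 8.20 ± 0.224 CPM and DLGAP5, a spindle protein, from 189 ± 10.8 to 93.3 ± 5.35 CPM (SD, n = 4). MKI67, the proliferation marker Ki-67, chosen after its values were seen, fell from 1748 ± 77.3 to 906 ± 43.1 CPM. GINS4, a subunit of the replicative helicase complex, fell from 38.4 ± 2.97 to 17.5 ± 1.26 CPM and RFC5, a clamp loader subunit, from 125 ± 5.73 to 62.7 ± 1.55 CPM, with non-whole counts in 7 libraries. CCNE1, which encodes cyclin E1, was the G1/S member that did not pass (log2 change 0.08 ± 0.0566 SE, edgeR adjusted p = 0.231). Camera gave adjusted p = 5.96e-23 for G2/M (adjusted p = 0.045 with an estimated correlation) and adjusted p = 7.61e-21 for G1/S (adjusted p = 0.024 with an estimated correlation). In homologous recombination and the Fanconi anaemia pathway, which repair DNA breaks and crosslinks, 29 of 36 tested members fell and 1 rose (30 and 1 adjusted over the list alone), with a median of -0.48. The nuclease EXO1 fell from 72.2 ± 4.65 to 34.6 ± 1.07 CPM and the helicase BLM from 65.8 ± 5.20 to 32.2 ± 1.06 CPM, while ATM, a kinase of the DNA break response, rose from 99.1 ± 7.37 to 134 ± 7.27 CPM. The call of that list (camera adjusted p = 1.10e-09) was lost with the correlation estimated (adjusted p = 0.066 with an estimated correlation).

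Transcripts of replication-dependent histone genes normally accumulate during DNA synthesis. Of 19 genes of that list in the files only 6 had enough counts to be tested, so most of the list is not covered. The tested genes moved mostly opposite to the replication genes. Of 6 tested members 5 rose and none fell (5 adjusted over the list alone), with a median log2 change of 0.98. H2BC5 rose from 7.48 ± 1.08 to 23.9 ± 1.5 CPM and H2BC4 from 1.86 ± 0.204 to 5.07 ± 1.14 CPM (SD, n = 4). Camera called the list with the preset correlation (adjusted p = 0.00273; adjusted p = 0.097 with an estimated correlation).

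Nuclear-encoded subunits of oxidative phosphorylation fell in 22 of 40 tested members and rose in 1 (22 and 1 adjusted over the list alone), with a median log2 change of -0.15. COX6C, a cytochrome oxidase subunit, fell from 97.7 ± 7.87 to 70.4 ± 1.27 CPM and UQCRQ, a complex III subunit, from 23.7 ± 2.46 to 17.2 ± 2.02 CPM, while NDUFA2 of complex I rose from 10.1 ± 1.13 to 13.2 ± 1.86 CPM (SD, n = 4). The camera adjusted p was 0.00123 (adjusted p = 0.15 with an estimated correlation). Glycolysis and hypoxia targets had 14 of 31 tested members up and 4 down (15 and 4 adjusted over the list alone). The glucose transporter gene SLC2A3 rose from 15.8 ± 1.82 to 42.1 ± 1.39 CPM and the stress-induced NDRG1 from 64.9 ± 3.82 to 158 ± 7.05 CPM, but LDHA, the lactate dehydrogenase of glycolytic cells, fell from 1236 ± 34.8 to 853 ± 15.4 CPM. Camera called the list (adjusted p = 0.0171; adjusted p = 0.074 with an estimated correlation). Cholesterol synthesis genes rose in 12 of 28 tested members and fell in 8 (13 and 9 adjusted over the list alone; camera adjusted p = 0.307). HSD17B7 rose by a log2 change of 0.56, and EBP, a sterol isomerase, fell by 0.57 on the log2 scale.

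The list of cytosolic ribosomal proteins, which also holds the elongation factor genes EEF2 and EEF1B2, rose slightly. Of 47 tested members 26 rose and 5 fell (26 and 5 adjusted over the list alone), with a median log2 change of 0.11. RPS19 rose from 256 ± 8.6 to 352 ± 18.1 CPM and the elongation factor gene EEF2 from 2677 ± 97.8 to 3547 ± 78.3 CPM (SD, n = 4), while RPS28 fell by 0.27 on the log2 scale, with non-whole counts in 6 libraries. The camera call (adjusted p = 0.000474) was lost with the correlation estimated (adjusted p = 0.43 with an estimated correlation). Ribosome biogenesis genes and MYC targets were mixed, with 10 of 35 tested members up and 14 down (10 and 14 adjusted over the list alone; camera adjusted p = 0.284). The nucleolar genes GAR1 and FBL fell by 0.57 and 0.47 on the log2 scale, while RRP12 rose by a log2 change of 0.66. MYC, chosen after its values were seen, rose from 303 ± 14.7 to 413 ± 11.6 CPM. Splicing factors fell in 28 of 38 tested members and rose in 2 (29 and 2 adjusted over the list alone), with a median of -0.26. SRSF7 fell from 159 ± 5.75 to 94.0 ± 2.79 CPM and SNRPD1, a core snRNP protein gene, from 163 ± 9.22 to 102 ± 1.61 CPM, while CLK1, a kinase that phosphorylates SR proteins, rose from 18.6 ± 0.884 to 24.9 ± 1.87 CPM. Camera gave an adjusted p of 8.15e-08 for the list (adjusted p = 0.074 with an estimated correlation).

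Immediate early and AP-1 genes, which respond rapidly to stress and growth signals, rose in 18 of 30 tested members and fell in 6 (19 and 6 adjusted over the list alone), with a median log2 change of 0.61. Besides JUN, the nuclear receptor gene NR4A1 rose from 7.58 ± 2.07 to 26.1 ± 1.16 CPM (SD, n = 4), with a non-whole count in 1 library, while the transcription factor gene KLF2 fell from 11.8 ± 1.14 to 3.27 ± 0.483 CPM. Camera called the list (adjusted p = 0.000587; adjusted p = 0.074 with an estimated correlation). NF-kB and inflammatory genes rose in 10 of 17 tested members and fell in 2 (10 and 2 adjusted over the list alone; camera adjusted p = 0.0208; adjusted p = 0.12 with an estimated correlation). CXCL8, the chemokine interleukin-8, rose from 0.395 ± 0.092 to 1.80 ± 0.275 CPM on 25 and 96 summed counts, and ICAM1, an adhesion molecule, from 5.70 ± 0.707 to 12.02 ± 0.433 CPM. TNFAIP3, the NF-kB inhibitor A20, fell by 0.34 on the log2 scale (edgeR adjusted p = 0.0382). The TNFAIP3 call was lost with DESeq2 (adjusted p = 0.0728) and without untreated replicate 1 (0.0503), untreated replicate 3 (0.0767), untreated replicate 4 (0.0726), CB-5083 replicate 2 (0.11) or CB-5083 replicate 4 (0.161). Interferon-stimulated genes rose in 6 of 25 tested members and fell in 4 (6 and 4 adjusted over the list alone; camera adjusted p = 0.629). Their median log2 change was above 0 (0.04) and their mean just below it (-0.000804). STAT2, an interferon signalling factor with a non-whole count in 1 library, and TAP1, a peptide transporter, rose by log2 changes of 0.73 and 0.61, and PSMB9, an immunoproteasome subunit, fell from 1.91 ± 0.591 to 0.770 ± 0.169 CPM.

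Wnt targets and intestinal stem cell genes fell in 9 of 19 tested members and rose in 2 (9 and 2 adjusted over the list alone), with a median log2 change of -0.14. NOTUM, a secreted Wnt inhibitor and Wnt target, fell from 10.0 ± 0.796 to 3.67 ± 0.379 CPM and TNFRSF19 from 2.36 ± 0.375 to 1.11 ± 0.122 CPM (SD, n = 4). AXIN2, a feedback inhibitor of Wnt signalling chosen after its values were seen, fell from 57.1 ± 4.00 to 33.9 ± 2.85 CPM. Against these, CCND1, which encodes cyclin D1, rose from 553 ± 13.3 to 850 ± 16.5 CPM. Camera called the list (adjusted p = 0.0106; adjusted p = 0.074 with an estimated correlation). Colonic epithelial differentiation genes rose in 6 of 13 tested members and fell in 2 (7 and 3 adjusted over the list alone; camera adjusted p = 0.0902). The cell adhesion gene CEACAM1 rose from 1.254 ± 0.157 to 2.61 ± 0.389 CPM and KRT18 from 878 ± 26.6 to 1425 ± 71.6 CPM, but KRT20, a marker of mature colonocytes, fell from 2.89 ± 0.608 to 1.67 ± 0.621 CPM. Genes of epithelial-mesenchymal transition and migration rose in 14 of 23 tested members and fell in 2 (14 and 2 adjusted over the list alone). The list mixes epithelial genes, such as CDH1 and CLDN7, with mesenchymal genes, such as VIM and FN1. Its direction therefore does not say whether a transition took place. PLAU, the urokinase gene, rose from 31.6 ± 1.55 to 82.8 ± 3.14 CPM and LAMB3, a laminin subunit of epithelial basement membranes, from 37.8 ± 2.20 to 64.6 ± 2.45 CPM, whereas FN1, the fibronectin gene and a mesenchymal marker, fell from 36.4 ± 1.82 to 18.1 ± 1.42 CPM. The camera adjusted p was 0.000362 (adjusted p = 0.075 with an estimated correlation).

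**Figure D2:**
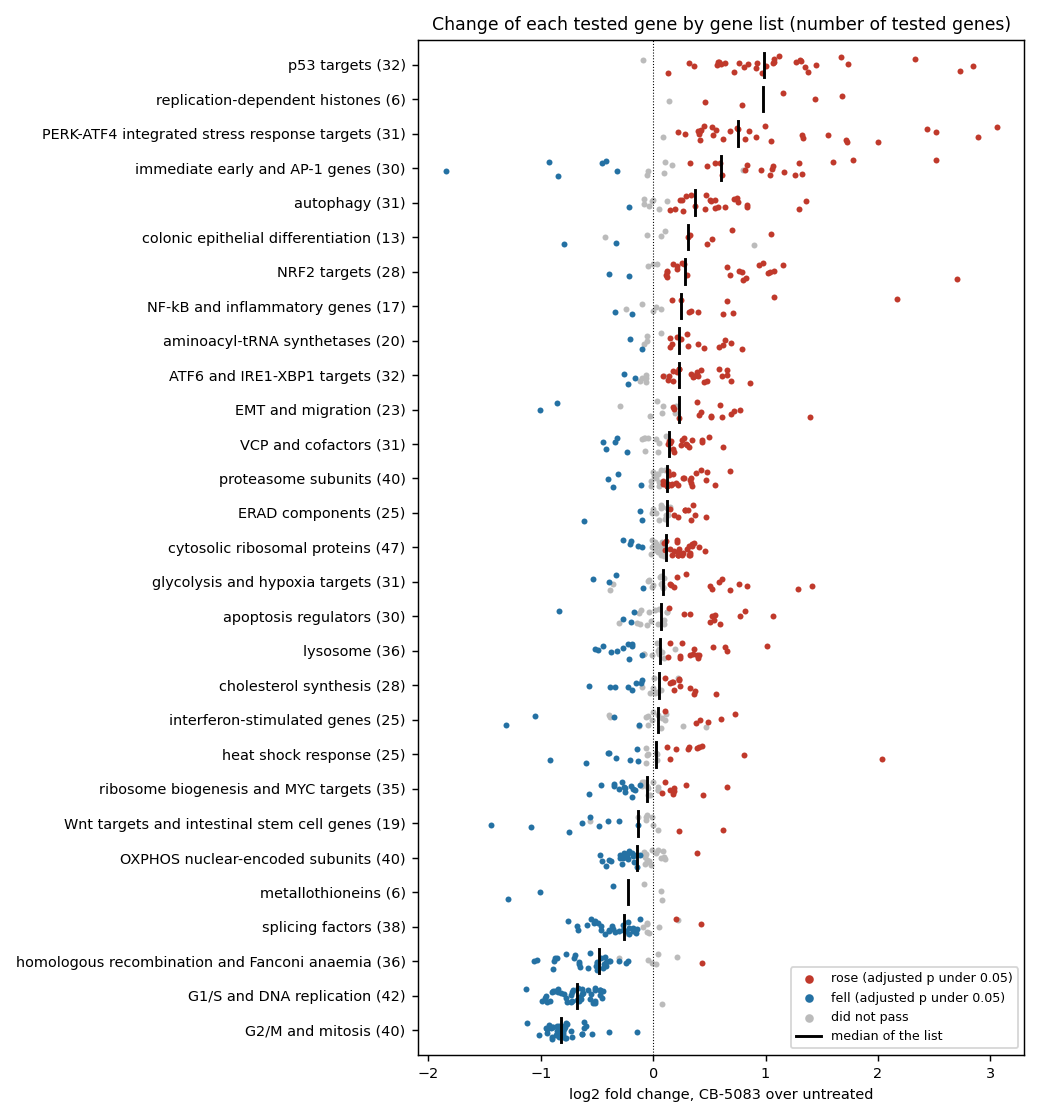
Change of each tested gene in the 29 tested gene lists. The x axis gives the log2 fold change of CB-5083 over untreated; each point is 1 gene (red, rose; blue, fell; grey, did not pass an adjusted p of 0.05), the black bar is the median of the list, and the number of tested genes follows the list name. The p53 targets (median 0.98) and integrated stress response targets (0.75) lie almost wholly to the right of 0, and the G1/S (-0.68) and G2/M (-0.82) genes to the left.

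Camera called 21 of the 29 tested lists with its preset inter-gene correlation of 0.01, 15 up and 6 down. With the correlation estimated per list 7 calls held, those of the integrated stress response, proteasome, autophagy, NRF2, p53, G1/S and G2/M lists. Among the 34 other splits of the 8 libraries into 4 and 4, 15 to 20 lists were called with the preset correlation in the 16 splits that kept 3 libraries of each group together, and 0 to 3 in the other 18; none was called with estimated correlations. The list of mitochondrially encoded genes was not analysed here.

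Markers of other cell types were also read. Neural markers, the highest of the 6 marker lists, summed to 118 ± 5.84 CPM in untreated and 80.4 ± 1.45 CPM in CB-5083 libraries (SD, n = 4). Most of this came from TUBB3, a tubulin gene also transcribed in many cancer lines, which fell from 101 ± 6.40 to 59.8 ± 2.86 CPM, and MAP2 rose from 15.1 ± 0.823 to 19.5 ± 1.94 CPM. The fibroblast markers COL1A1, from 21.1 ± 2.69 to 25.4 ± 2.05 CPM, and COL6A3, from 0.698 ± 0.347 to 1.67 ± 0.711 CPM, both rose. No tested leukocyte, endothelial or hepatocyte marker passed; their sums were 3.92 and 4.84, 28.2 and 27.4, and 21.2 and 19.8 CPM in untreated and CB-5083 libraries. Erythroid markers, summing to 1.31 and 0.900 CPM, were too low to test.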

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

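Of 202 groups of 4 libraries examined, 9 held a library far from the other 3, where chance gives about 10.1, so the number does not exceed chance. The tests weighing the MTRNR2L genes below were chosen after the result was seen.

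CDKN1A was at 498 CPM in CB-5083 replicate 1, against 479 to 481 in the other CB-5083 libraries. TNS2 was at 18.3 CPM in untreated replicate 1, against 25.2 to 25.9 in the others. PSAP stood at 468 CPM in untreated replicate 4, above the 435 to 440 of the others. PMAIP1 stood at 51.0 CPM in untreated replicate 2, below the 55.5 to 56.4 of the others. NOTUM reached 4.24 CPM in CB-5083 replicate 4, with the others at 3.45 to 3.53. KRT18 was low in untreated replicate 3, at 839 CPM, with the others at 887 to 896. H2BC5 was low in CB-5083 replicate 2, at 21.6 CPM, with the others at 24.5 to 24.7. H2BC4 was low in untreated replicate 2, at 1.56 CPM, with the others at 1.94 to 2.00. The MTRNR2L genes took 1.06% of the counts in CB-5083 replicate 4 and 1.12 to 1.13% in the other CB-5083 libraries.

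The MTRNR2L genes fell with CB-5083 in 5 of 6 tested copies and rose in none, with MTRNR2L8 going from 7483 ± 356 to 6440 ± 198 CPM (SD, n = 4; edgeR adjusted p = 2.55e-06) and MTRNR2L2 from 5315 ± 335 to 4603 ± 146 CPM, with non-whole counts in 8 and 7 libraries. A candidate explanation is that these reads come from the mitochondrial 16S rRNA and were assigned to its nuclear copies. Over the 7 copies in the files, identity to the 16S rRNA rose with the mean count (Spearman rho = 0.893, exact permutation p = 0.0123; Pearson r with the log2 count = 0.904, exact permutation p = 0.00694; r = 0.91 without the 2 copies farthest from the median identity), which is consistent with that explanation. The copies are not independent, and the identity of MTRNR2L2 (98.5%) and MTRNR2L9 (90.7%) rests on 65 and 75 aligned bases; MTRNR2L9 had non-whole counts in 8 libraries. If the reads come from the 16S rRNA, its fall in the cells and a lesser carry-over into these libraries both stay open. A change in transcripts of the nuclear copies themselves stays open too and was not tested.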

How the results depend on the processing

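The planned settings were chosen before the data were examined; GC and length correction, thinned counts, unrounded counts and the removal of genes with non-whole counts were added after the data were seen. Across all 19 alternative fits 82.6 to 99.9% of the called genes stayed called, the lowest share where genes with non-whole counts were removed, and none was called with the opposite sign. Without a low-count filter 294 genes were higher and 267 lower by 2-fold or more (210 and 165 with it), a setting that admits genes of few counts. With an estimated correlation 7 lists were called by camera (21 with the preset value), and fry called 26. Leaving out 1 library at a time gave 3264 to 3482 genes higher and 3232 to 3434 lower, 212 to 235 higher and 160 to 204 lower by 2-fold or more, and 21 called lists each time. Same-numbered libraries deviated together only weakly (correlations 0.00993 to 0.0489), and 2 of 8 samples correlated best with their own number. Any pairing by number was thus weak, though it is not excluded. With the replicate number as a block 3564 genes were higher and 3553 lower, 210 and 165 by 2-fold or more, and 21 lists were called. Of the 96 named genes 93 kept their call in every one of the 19 alternatives that tested them, and SDF2L1, GPNMB and TNFAIP3 lost it in some; no sign reversed. Of the list results under the alternatives 560 kept their side of the threshold, 14 lost the call, all with an estimated correlation, and 6 gained one: with fry the lysosome, apoptosis, ribosome biogenesis, colonic differentiation and metallothionein lists, and with limma-voom the colonic differentiation list (adjusted p = 0.0375). Depth limits small changes of genes with few counts. Of simulated 1.5-fold changes, 65% of 20 genes below the median mean count were called and 100% of 29 genes above it. The adjusted threshold was stricter in that simulation than in the data. The settings made for values other than counts were not run, since the files hold counts.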

Other observations

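The gene families and keratins in this part were chosen after the data were seen, as were the tests of the cell cycle and histone patterns; the counts of other splits were planned. Keratin genes other than KRT7, KRT80 and KRT18 also changed with CB-5083. KRT8 rose from 2098 ± 32.7 to 3020 ± 118 CPM (SD, n = 4), KRT19 from 646 ± 37.2 to 902 ± 36.2 CPM, and the hair keratin gene KRT81 from 0.631 ± 0.186 to 6.88 ± 0.333 CPM, with non-whole counts in 3 libraries. KRT10 fell from 12.6 ± 1.33 to 9.06 ± 0.246 CPM and KRT23 from 42.2 ± 4.88 to 32.7 ± 3.62 CPM. Of 14 tested keratin genes 8 rose and 4 fell, but the family did not pass camera (adjusted p = 0.115 over 146 families of genes sharing a symbol stem).

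Among those 146 families camera called 12, 4 up and 8 down, and none with an estimated correlation. Nucleoporins fell in 18 of 22 tested members and rose in none, with NUP107 going from 153 ± 9.08 to 107 ± 4.51 CPM and NUP50 from 241 ± 6.11 to 185 ± 6.69 CPM (SD, n = 4; family adjusted p = 0.00104, and adjusted p = 0.55 with an estimated correlation). Large-subunit mitochondrial ribosomal proteins fell in 27 of 49 tested members, MRPL20 among them (49.0 ± 3.97 to 33.4 ± 1.43 CPM), while MRPL10 rose (family adjusted p = 0.0008, and adjusted p = 0.55 with an estimated correlation). Those of the small subunit (MRPS) fell in 16 of 29 tested members and rose in 1. Their family adjusted p by camera was 0.032, and 0.55 with an estimated correlation. The LSM family, which holds Sm-like proteins of RNA processing, fell in 10 of 13 members, with LSM6 going from 17.1 ± 1.38 to 8.37 ± 0.295 CPM, while LSM10 rose (family adjusted p = 0.0252, and adjusted p = 0.55 with an estimated correlation). Golgins rose in 10 of 19 members, but 5 of the 10 had non-whole counts in all 8 libraries and are uncertain. The other 5 had whole counts throughout, among them GOLGA2, which rose from 79.5 ± 3.52 to 112 ± 2.64 CPM, and GOLGA3, from 110 ± 2.78 to 152 ± 3.35 CPM. GOLGA8H, with non-whole counts in all 8 libraries, fell (family adjusted p = 0.0326, and adjusted p = 0.55 with an estimated correlation).

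The fall of the replication and mitosis genes kept its size when technical trends were removed. Over the 82 tested members of both lists the median log2 change was -0.78 (SD over genes 0.199). It was -0.753 after correction for GC content and transcript length, which argues against that bias as the whole cause. Across genes the log2 change was hardly related to GC content (Spearman rho = -0.019) or length (0.045). With every library thinned to the smallest total the median was -0.776. The fit already scales by library totals, so thinning could hardly move the median and does not decide on depth. A response of the cells to CB-5083 stays open as an untested explanation.

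The rise of the tested clustered histone genes went against that fall. The 9 tested clustered genes, which include those of the list, were set beside 13 other tested histone genes, mostly variants outside the clusters. H2AW, counted among the 13, is a gene of a smaller cluster and did not pass (log2 change -0.40, edgeR adjusted p = 0.0605). Of the 9 clustered genes 7 rose and none fell, with H4C15 uncertain because of non-whole counts in 6 libraries. Of the other 13 genes 10 fell and none rose, with H2AX going from 184 ± 21.4 to 89.9 ± 4.08 CPM and H2AZ1 from 377 ± 14.6 to 227 ± 10.1 CPM. The median log2 change of the list after correction for GC content and length was 0.984, and 0 of its 5 risen genes had a non-whole count in any library, so the tables argue against these biases and, as far as non-whole counts mark shared reads, against reads shared between histone copies. Carry-over of histone RNA without a poly(A) tail could raise these genes too, and this cannot be told apart: the summed level of the 38 clustered genes too low to test went from 5.62 ± 1.11 to 6.19 ± 1.19 CPM (log2 change 0.14, exact permutation p = 0.514), on a mean of 2.26 counts per gene and library. A response of the cells to CB-5083 stays open as well and was not tested.

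The 35 splits of the 8 libraries into 4 and 4, the real one included, test whether chance could give these numbers. For each of the gene counts, 1 of the 35 splits gave a number as large, the real one: 3504 genes higher, 3498 lower, and 210 and 165 by 2-fold or more, against a highest of 0 genes among the other splits. For the lists called by camera, 1 split gave as many as the real 21, but the highest other split gave 20. The 16 splits that kept 3 libraries of each group together, and so hold part of the real contrast, gave 15 to 20 lists, and the 18 splits that mixed the groups evenly gave 0 to 3. With an estimated correlation the real split called 7 lists and the highest other split 0. For the gene counts only the real split gave such numbers, the smallest share that 35 splits can give. Every other split holds treated and untreated libraries on each side, which widens the spread within its groups and lowers its calls. The share is low, but it does not exclude chance. For lists called with the preset correlation the lead over the other splits was 1 list, so that number hardly tells the real grouping from those 16 splits.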
